A study of Mus musculus with 8 samples.

How the data were processed

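RNA was taken from mouse bone marrow-derived dendritic cell cultures treated with vehicle or recombinant S100A8/A9, with 4 libraries per group. The labels name the cells dendritic cells in the cell type field and protocol, while the sample titles carry an abbreviation usually used for macrophages, and the cell type field was followed. Poly(A) RNA was fragmented, reverse transcribed with random priming and sequenced on an Illumina instrument, per the labels' protocols. No strand marking is stated there, so reads of overlapping or antisense genes cannot be told apart. The submitters' processing notes name HISAT2, featureCounts, Subread, DESeq2 1.34.0 and the mm10 build, without saying which step used which.

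The deposited values are FPKM per Ensembl gene, a unit inferred from the values because no header or label states it. The authors made 2 tables. Replicates 1 to 3 of both groups list 55450 genes each, with FPKM sums from 282921 to 303660. Replicate 4 of both groups lists 24848 genes, with sums of 331268 and 344166, and 24388 genes are in both tables. In replicate 4, 98.55% and 98.77% of the deposited FPKM values worth up to 20 reads were whole multiples of 1 read within 0.01 reads, given each gene's exon length. In replicates 1 to 3 this held for 5.33% to 6.14%, so the authors did not make the 2 tables alike, and the depth of replicates 1 to 3 is a rough estimate from the commonest low value. Correlations of log2(FPKM + 1) between libraries were 0.982 to 0.993 in the first table, 0.994 in the second and 0.929 to 0.936 across tables. No 2 libraries were identical, and the series table held the same values as the per-sample tables.

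The design chosen before the data were examined was a quasi-likelihood test on counts of all 8 libraries, with limma-trend on log2(value + 1) if no counts were found. Because the values are FPKM from 2 separately normalized tables, the test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), on replicates 1 to 3 with group as the term, for genes with at least 1 FPKM in at least 3 of the 6 libraries. FPKM were used as deposited. Fold changes on the log2(FPKM + 1) scale understate changes of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The fit of all 8 libraries was run as an alternative. Folds in the text are geometric means of the within-pair FPKM ratios.

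Groups share replicate numbers, and the labels do not say what a number marks. Before the calls of the fits were compared, deviations from the group means were correlated between groups over genes. Libraries of the same number gave 0.59, 0.25 and 0.52, and libraries of different numbers gave values from -0.53 to -0.01, so the numbers were taken to pair the libraries. The fit with the replicate number as a block is therefore printed beside results it changes.

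The 37 gene lists, for pathways and for markers of cell types the cultures could hold, were fixed before the data were examined. Lists with at least 5 tested genes were tested with limma's camera at its preset correlation of 0.01, adjusted over 31 lists, and again with an estimated correlation and with fry. The rule for named genes took the 8 with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 FPKM and no overlap between groups, leaving out predicted gene models, plus 15 fixed genes and up to 4 called members per list or, where none was called, the 1 with the smallest p. The rule had been written for CPM and the group-only fit. As that fit called 0 genes, the rule was applied to the blocked fit and to FPKM, a choice made after the data were seen. It found 42 genes, of which 3 predicted models were left out, and no named gene that fell. The report names other genes only as stated there, from counts over a list alone, or as background on a list.

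Gene symbols came from a table of Ensembl gene names, and mm10 positions and exon lengths from the GENCODE annotation of that build. All 55450 genes of the first table had a symbol, as did 24388 of the 24848 in the second. Reads in replicate 4 were computed from FPKM, exon length and the value of 1 read. They were not tested as counts.

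The fits were tested on simulated data with 200 of 11387 genes changed, in 5 runs. For changes of 3-fold, 89.3% of changed genes were recovered with the block and 91.4% without it. For 2-fold these were 67.9% and 55.4%, and for 1.5-fold 0% and 0%. The real blocked fit called some genes with smaller changes than 1.5-fold, with a log2 change as low as 0.488 among called genes outside the lists. The simulated shares therefore need not hold for the real data. These figures are for genes drawn at random from all tested genes. With the 46 interferon-stimulated genes among the changed ones at 3-fold, 68.7% of the list was recovered with the block and 35.7% without it. Their median residual SD without the block was 0.476 against 0.17 over all genes. In the real data Ifit1 and Ifit2, at 3.35-fold and 3.84-fold, had adjusted p-values of 0.828 and 1 without the block. The simulated change was the same in each replicate, while the real one differed between replicates. The simulated data kept the replicate shifts, with same-number correlations of 0.65, 0.46 and 0.63 in the mean. False calls were at most 3.5% of calls. Changed lists were called in 5 of 5 runs and random lists in 0. The noise was drawn independently for each gene and the lists at random from all genes. These runs therefore do not show how often camera calls a list whose genes vary together.

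Alternatives covered other scalings, the filter, the pseudocount (0.5 and 0.1), the block, genes in both tables, all 8 libraries, left-out libraries, stricter thresholds and other list tests. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the plots.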

Results

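Messenger RNA was sequenced from cultures that the labels describe as dendritic cells grown from the bone marrow of mice with Sjögren's syndrome dry eye, a model of an autoimmune disease of the tear and salivary glands. The cultures received either phosphate-buffered saline, called vehicle here, or recombinant S100A8/A9, a calcium-binding protein pair that myeloid cells release in inflammation. Each group held 4 libraries, numbered 1 to 4. Replicates 1 to 3 of both groups shared 1 expression table and replicate 4 of both groups came from a second, separately made table, so tests were run on replicates 1 to 3 and the replicate 4 values are given beside them. The replicate 4 values implied about 31900000 reads for vehicle and 33400000 reads for S100A8/A9. For replicates 1 to 3 the low values gave rough estimates between 22800000 and 25700000 reads. The libraries of the first table held between 11180 and 11487 genes at 1 FPKM or more, FPKM being fragments scaled to transcript length and library depth. The labels do not say that the replicates came from separate animals or cultures. Mean log2(FPKM + 1) of neutrophil markers in replicates 1 to 3 was 2.68, 3.72 and 4.45 with vehicle, and 2.80, 3.73 and 4.45 with S100A8/A9. These values argue against replicate numbers being technical repeats of 1 RNA sample. The p-values without the block measure the spread between these libraries. Those with the block measure the spread of the within-pair differences, which may still be technical.

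The comparison of S100A8/A9 with vehicle asks which signaling programs the protein pair engages in these cultures. Whether they were mainly dendritic cells, as the cell type field says, was not tested. In vehicle replicates 1 to 3 mean log2(FPKM + 1) was 6.63, 5.76 and 5.08 for macrophage markers. It was 4.2, 4.23 and 4.41 for pan dendritic cell markers. Levels of different genes do not give the share of a cell type. Interferon-stimulated genes were higher with S100A8/A9 in replicates 1 to 3. All 46 tested members of this list had higher FPKM with S100A8/A9 than with vehicle in each of the 3 pairs, with a median log2 difference of 1.02. The median was 1.41 in replicate 1, 0.92 in replicate 2 and 0.72 in replicate 3. The mean log2(FPKM + 1) of the list was 3.32 ± 0.27 (SD, n = 3) with vehicle and 4.35 ± 0.55 (SD, n = 3) with S100A8/A9. A two-sided exact permutation test of this mean, which ignores the pairs, gave p = 0.1, the smallest that 3 libraries against 3 allow. An exact sign-flip permutation test over the 3 pairs gave p = 0.25, the smallest that 3 pairs allow. With the replicate number as a block, 26 of the 46 members rose past the adjusted threshold over all genes, none fell and 20 did not pass. Adjusted over the list alone, 46 members passed with the block and 41 without it. The list was called by limma's camera with its preset correlation of 0.01 (adjusted p = 1.2e-59), but not with an estimated correlation (adjusted p = 0.37 with an estimated correlation, 0.40 with the block).

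Ifit2, which encodes an interferon-induced RNA-binding protein, had the largest change among the genes named by rank. Its expression was 5.51 ± 2.28 FPKM (SD, n = 3) with vehicle and 23.5 ± 14.9 FPKM (SD, n = 3) with S100A8/A9, a 3.84-fold geometric mean of the within-pair ratios. The log2 change was 1.76 ± 0.18 (SE), with an adjusted p of 0.0289 in limma with the replicate block. Ifit1 lies near Ifit2 on chromosome 19 and encodes a sensor of uncapped or incompletely capped RNA. It rose from 8 ± 2.92 to 27.5 ± 12.0 FPKM (SD, n = 3 each), or 3.35-fold, with an adjusted p of 0.00917 in limma with the block. Ifit1 (ENSMUSG00000034459) lies on the forward strand of chromosome 19 from 34640871 to 34650009, and Ifit2 (ENSMUSG00000045932) from 34550694 to 34576419, in mm10. Rsad2, which encodes the antiviral enzyme viperin, rose 2.96-fold and its neighbor Cmpk2, a mitochondrial nucleotide kinase, rose 2.92-fold. Oasl2 and Oasl1, relatives of the oligoadenylate synthetases, rose 2.79-fold and 2.70-fold. Rnf213, a large ubiquitin ligase outside the fixed lists, rose 2.62-fold, and Rtp4 rose 2.53-fold. Slfn5 rose 2.60-fold and Usp18, which removes ISG15 from proteins and restrains interferon receptor signaling, rose 2.45-fold. Adjusted p-values of these 10 genes in limma with the block lay between 0.00917 and 0.0324. None of the 10 calls held with upper-quartile factors (adjusted p from 0.0553 to 0.129), without the filter (0.755 to 0.839) or with all 8 libraries and the block (0.173 to 0.348). Only Ifit1, Rtp4 and Usp18 kept theirs with median-of-ratios factors or quantile normalization, and only Ifit1, Rsad2, Cmpk2 and Usp18 without replicate 3. Ifit, Oas, Gbp, Slfn, Trim30 and Ifi200 genes have close relatives that can share reads, so values of single members of these families are uncertain.

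**Figure D1:**
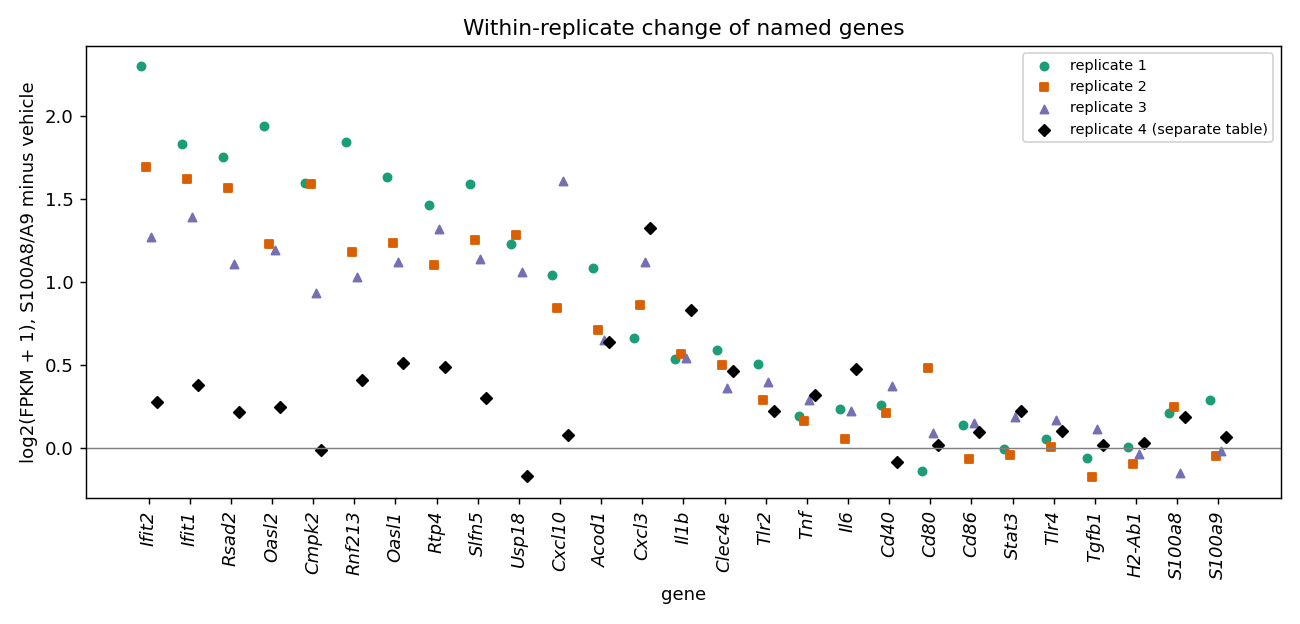
Differences in log2(FPKM + 1) between S100A8/A9 and vehicle for named genes, with 1 point per replicate pair and replicate 4, from the separate table, in black. The interferon-stimulated genes from Ifit2 to Usp18 on the left lie between 0.93 and 2.30 in replicates 1 to 3, and their replicate 4 values lie between -0.17 and 0.51.

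Across all 11387 genes tested, limma without the block called 0 genes, with 344 at an unadjusted p under 0.05 and a smallest adjusted p of 0.736. The 344 are fewer than the share of 0.05 of genes that no change at all would give on average. With the block, 59 genes passed, of which 57 rose and 2 fell. With it 908 genes were at an unadjusted p under 0.05 in limma, more than that share. The block was used because libraries of the same number deviated together. The 2 genes that fell were Gm10718 and Gm23935, both predicted models named after their values were seen, with log2 changes of -0.85 and -0.71. The count of 59 was not stable. It was 7 without replicate 3 (5 of them among the 59), 40 without replicate 1, 98 without replicate 2, 0 without the filter and 0 with all 8 libraries and the block. Over other scalings it was 39 after scaling to a common sum, 3 with median-of-ratios factors or quantile normalization and 0 with upper-quartile factors.

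Acod1, which encodes the enzyme that makes itaconate from a citric acid cycle intermediate, rose in the blocked fit. Its expression was 88.97 ± 18.7 FPKM (SD, n = 3) with vehicle and 155 ± 14.2 FPKM (SD, n = 3) with S100A8/A9. The within-pair ratios were 2.14, 1.64 and 1.57 in replicates 1 to 3, and the log2 change was 0.81 ± 0.092 (SE). The adjusted p was 0.0326 in limma with the block and 0.736 without it. The call was lost without replicate 3 (adjusted p = 0.0773), without the filter (0.839), with all 8 libraries and the block (0.107), and with median-of-ratios factors (0.10), upper-quartile factors (0.132) or quantile normalization (0.128). Acod1 (ENSMUSG00000022126) spans 103046977 to 103056573 on the forward strand of chromosome 14 in mm10. In the list of itaconate and immunometabolism genes, 1 of 20 tested members rose and 19 did not pass. Adjusted over the list alone, 6 members passed with the block, including Irgm1, Gch1 and Nos2, and 2 without it. The list itself was not called (adjusted p = 0.09, and 0.05 with the block, which before rounding lay above the threshold).

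Cxcl3, a neutrophil-attracting chemokine, rose 2.08-fold in the blocked fit (adjusted p = 0.0402), from 3.89 ± 1.45 to 8.06 ± 3.06 FPKM (SD, n = 3 each). Cxcl10, an interferon-inducible chemokine for activated T cells, rose 2.52-fold (adjusted p = 0.0421). Without replicate 3 their adjusted p-values were 0.117 and 0.0729, and neither call held with median-of-ratios factors, upper-quartile factors or quantile normalization, without the filter or with all 8 libraries, nor did that of Cxcl10 without replicate 1 (0.0633). Cxcl3 and Cxcl10 were the 2 members of the 19 tested chemokines that rose, and the list was called (median 0.13, adjusted p = 0.017, and 0.61 as the adjusted p with an estimated correlation). Adjusted over the list alone, 3 chemokines passed with the block and 1 without it. The list's call was lost without vehicle replicate 2 (adjusted p = 0.18) or S100A8/A9 replicate 1 (0.61). The NF-kB target list was called (median 0.15, adjusted p = 0.00092, and 0.96 as the adjusted p with an estimated correlation), although 0 of its 26 tested members passed over all genes. Adjusted over the list alone, 4 of them passed with the block, namely Il1b, Clec4e, Sod2 and Saa3, and 0 without it. The list's call was lost without vehicle replicate 1 (adjusted p = 0.086), vehicle replicate 2 (0.099) or S100A8/A9 replicate 3 (0.33), where its median was -0.001. Clec4e, a receptor for mycobacterial glycolipids, was 1.41-fold higher with an adjusted p of 0.0531. The list of S100A8/A9 receptors and TLR4 signaling was called with a median of 0.095 over 30 genes (adjusted p = 0.032, and 0.68 as the adjusted p with an estimated correlation), with Tlr2 and Myd88 passing over the list alone with the block and 0 genes without it. Its call was lost without vehicle replicate 1 (adjusted p = 0.17), vehicle replicate 2 (0.087), S100A8/A9 replicate 2 (0.091) or S100A8/A9 replicate 3 (0.11), and with quantile normalization (0.085). The inflammasome list was called with a median of 0.15 over 18 genes (adjusted p = 0.032, and 0.42 as the adjusted p with an estimated correlation), with Il1b, Panx1 and Ninj1 passing over the list alone with the block and 0 genes without it. Its call was lost with all 8 libraries without the block (adjusted p = 0.058), and without vehicle replicate 2 (0.094), S100A8/A9 replicate 1 (0.50) or S100A8/A9 replicate 2 (0.075).

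MHC class I presentation was called as well (median 0.18, adjusted p = 6e-06, and 0.21 as the adjusted p with an estimated correlation). None of its 14 tested members passed over all genes. Adjusted over the list alone, 7 passed with the block and 2 without it, and the 7 included the peptide transporter genes Tap1 and Tap2, the tapasin gene Tapbp and the MHC class I transactivator Nlrc5. Tap1 was at 32.6 ± 3.73 FPKM with vehicle and 45.3 ± 0.694 FPKM with S100A8/A9 (SD, n = 3 each), with an adjusted p of 0.0914 with the block. MHC class II presentation was not called (adjusted p = 0.90, median 0.021 over 13 genes). H2-Ab1, an MHC class II beta chain, was at 469 ± 177 FPKM with vehicle and 458 ± 186 FPKM with S100A8/A9 (SD, n = 3 each).

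Among cytokines that favor Th17 cells, Il1b had within-pair ratios of 1.69, 1.61 and 1.52, but its adjusted p was 0.0631 with the block and 1 without it. Il1b was at 4.07 ± 2.48 FPKM with vehicle and 6.40 ± 3.60 FPKM with S100A8/A9 (SD, n = 3 each), so the spread between replicates exceeded the difference between groups. Il6 was at 1.14 ± 0.418 and 1.39 ± 0.334 FPKM (adjusted p = 0.845 with the block), and Tnf at 5.44 ± 0.254 and 6.46 ± 0.377 FPKM (adjusted p = 0.575 with the block; SD, n = 3 each). Tgfb1 was at 130 ± 5.12 and 127 ± 16.8 FPKM (SD, n = 3 each). Il23a and Il12b stayed below the filter, with at most 0.175 FPKM for Il23a and 0.661 FPKM for Il12b in replicates 1 to 3. The list of Th17-polarizing cytokines, with 8 tested genes and a median of 0.20, was called with the block (adjusted p = 0.0039) and not without it (adjusted p = 0.064), nor with an estimated correlation (adjusted p = 0.40 with the block).

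Stat3, a transcription factor downstream of IL-6 family cytokines, was at 34.3 ± 1.15 FPKM with vehicle and 35.5 ± 3.80 FPKM with S100A8/A9 (SD, n = 3 each), with an adjusted p of 0.932 with the block. Its log2 change of 0.04 became -0.03 with upper-quartile factors and -0.02 with quantile normalization. The JAK-STAT3 list was not called (median 0.10 over 22 genes, adjusted p = 0.076, and 0.05 with the block, which before rounding lay above the threshold). The co-stimulatory genes Cd40, Cd80 and Cd86 had adjusted p-values of 0.411, 0.866 and 0.886 with the block, and Tlr4 had 0.868. The maturation list, with 19 tested genes and a median of 0.06, was called with the block (adjusted p = 0.019) and not without it (adjusted p = 0.11), nor with an estimated correlation (adjusted p = 0.69 with the block). The list of NRF2 targets, which are antioxidant genes, behaved alike in this respect, with a median of 0.11, an adjusted p of 0.0022 with the block and 0.15 without it, and 0.40 as the adjusted p with an estimated correlation. S100a8 and S100a9, which encode the protein pair itself, had log2 changes of 0.10 and 0.07 and adjusted p-values of 0.863 and 0.914 with the block.

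**Figure D2:**
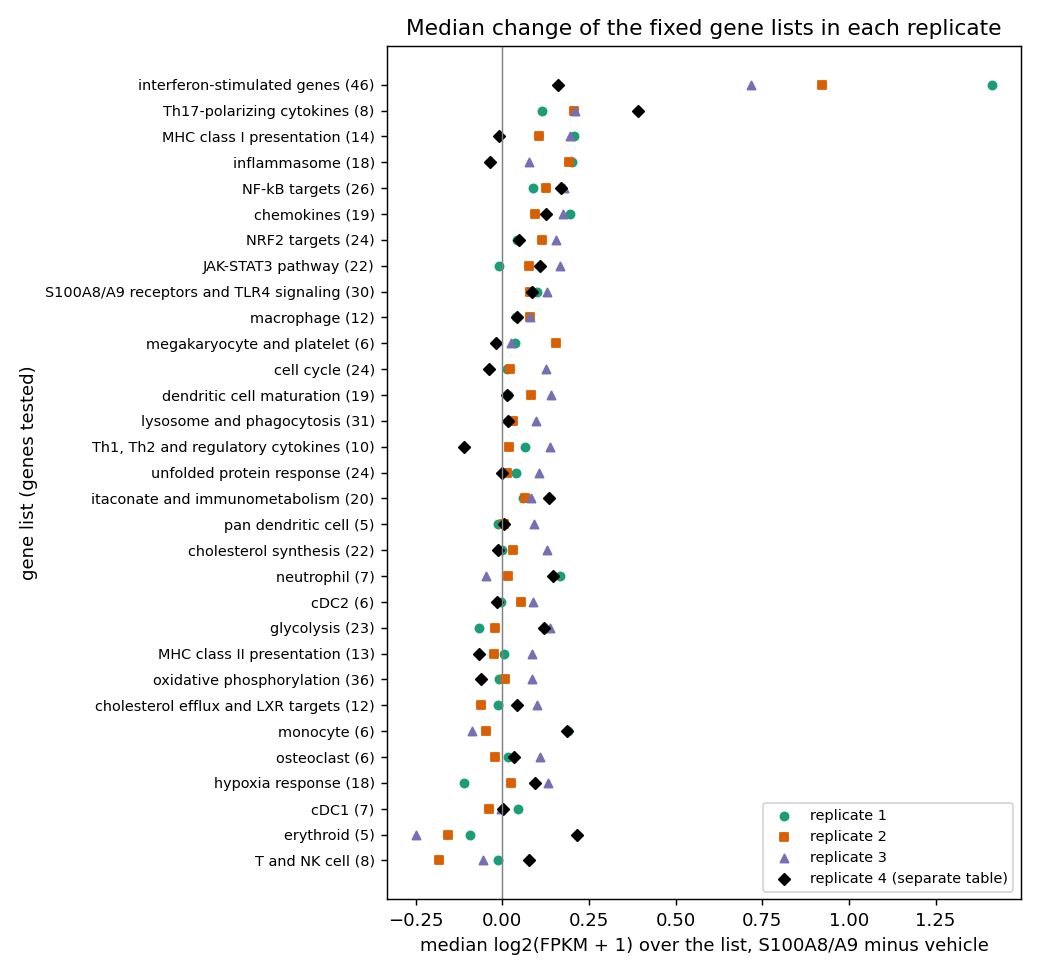
Median difference in log2(FPKM + 1) between S100A8/A9 and vehicle for each fixed gene list with at least 5 tested genes, with 1 point per replicate pair and the number of genes tested in parentheses. The interferon list stands at 0.72 to 1.41 in replicates 1 to 3 and at 0.16 in replicate 4.

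In all, 31 of the 37 fixed lists had at least 5 tested genes. Without the block camera called 6 lists, each higher with S100A8/A9, and with the block 11 lists, 9 higher and 2 lower. Both counts fell to 0 with an estimated correlation and with limma's fry for a shared direction. Camera with an estimated correlation has few residual degrees of freedom here. With the block it gave the same adjusted p of 0.40 for interferon-stimulated genes, NRF2 targets and erythroid markers. The Benjamini-Hochberg adjustment can tie lists in this way. Without the block its adjusted p was 0.21 for MHC class I presentation, 0.37 for interferon-stimulated genes and 0.96 for NF-kB targets. Its power was not tested, so whether a call was lost there for lack of power or for lack of a change cannot be told. The mixed fry test, which asks for changes in either direction, called 7 lists with the block, and not the interferon list (adjusted p = 0.052). Of these, NF-kB targets, S100A8/A9 receptors and TLR4 signaling, inflammasome and Th17-polarizing cytokines had an adjusted p of 0.0058 each. Chemokines, dendritic cell maturation and macrophage markers had 0.05 each, which before rounding lay below the threshold. Without single libraries the unblocked count lay between 4 and 17, with 12 higher and 5 lower without vehicle replicate 3. With any of the 4 other scalings the blocked fit called no list lower, giving 8 or 9 higher and 0 lower. The 2 lower lists were markers of T and NK cells (median -0.14, adjusted p = 0.042 with the block) and erythroid cells (median -0.13, adjusted p = 0.04 with the block), and both had an adjusted p of 0.40 with an estimated correlation and the block. None of their 8 and 5 tested members passed over all genes, and the hemoglobin gene Hba-a2 passed over the erythroid list alone. Of the marker lists, macrophage (median 0.071), neutrophil (0.028), monocyte (0.014), pan dendritic cell (0.035), cDC1 (-0.01), cDC2 (0.025), megakaryocyte and platelet (0.068) and osteoclast (0.003) lists were not called by camera with or without the block. Neither were glycolysis (0.023), oxidative phosphorylation (0.019), hypoxia response (0.003), cell cycle (0.064), unfolded protein response (0.046), cholesterol synthesis (0.032), cholesterol efflux and LXR targets (0.016), lysosome and phagocytosis (0.053) or the Th1, Th2 and regulatory cytokines (0.052). Camera gave a lower direction for several uncalled lists with medians above 0, such as MHC class II presentation, glycolysis, oxidative phosphorylation and the neutrophil and monocyte markers. For cDC1 and hypoxia response the median and the mean differed in sign. Plasmacytoid dendritic cell, mast cell and basophil, eosinophil, B and plasma cell, stromal and fibroblast, and stem and progenitor markers had 1 to 4 tested genes and were not tested as lists.

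In replicate 4 the interferon-stimulated genes had a median log2 difference of 0.16, and 35 of the 46 were higher with S100A8/A9. The MHC class I list had a median of -0.01 there, with 6 of 14 genes higher. The difference between replicate 4 and replicates 1 to 3 had a median of -0.24 for this list. The inflammasome list had a median of -0.035 in replicate 4, with 7 of 18 genes higher. Medians there were 0.17 for NF-kB targets, with 23 of 26 higher, 0.125 for chemokines, with 12 of 19 higher, 0.087 for S100A8/A9 receptors and TLR4 signaling, with 23 of 30 higher, and 0.39 for Th17-polarizing cytokines, with 7 of 8 higher. Such counts were not particular to called lists. Among lists not called, glycolysis had 21 of 23 genes higher in replicate 4, hypoxia response 15 of 18 and JAK-STAT3 16 of 22. Oxidative phosphorylation had 7 of 36 and cell cycle 7 of 24. The 2 lists called lower with the block ran the other way in replicate 4, with medians of 0.078 for T and NK cell markers (5 of 8 higher) and 0.22 for erythroid markers (4 of 5 higher). The difference between replicate 4 and replicates 1 to 3 was also computed for each list. For other lists the median of this difference was -0.10 for dendritic cell maturation, 0.19 for Th17-polarizing cytokines and 0.065 for NF-kB targets. It was 0.074 for glycolysis, 0.083 for neutrophil markers and 0.35 for erythroid markers. These lists are not the ones that differed most. The median difference was -0.19 for Th1, Th2 and regulatory cytokines, -0.13 for cell cycle, -0.12 for inflammasome and -0.12 for MHC class II presentation. For monocyte markers it was 0.17, for T and NK cell markers 0.125 and for hypoxia response 0.11. Replicate 4 is 1 pair with no spread of its own, so these differences are given without a test. Ifit1 was at 1.15 and 1.79 FPKM there, corresponding to about 97 and 159 reads, and its ratio was 1.56. Ifit2 had a ratio of 1.28 in replicate 4, Rsad2 1.23, Oasl2 1.20, Rtp4 1.45, Oasl1 1.78 and Rnf213 1.35, while Cmpk2 was at 0.98 and Usp18 at 0.87. Acod1 had a ratio of 1.57 in replicate 4, from about 3929 and 6448 reads. Il1b had a ratio of 1.80, from about 1772 and 3348 reads, and Cxcl3 had 3.40, from about 187 and 666 reads, while Cxcl10 had 1.19, from about 29 and 36 reads. Of the 57 genes called with the block that replicate 4 also listed, 50 had the same sign there, against 53.1% of all tested genes. Replicate 4 has 1 library per group in its table, so its differences have no replicate check. With all 4 pairs in 1 blocked fit, 0 genes were called by limma (931 at an unadjusted p under 0.05) and Acod1 had an adjusted p of 0.107. An exact sign-flip permutation test over the 4 pairs gave p = 0.125 for the interferon list mean, for Acod1 and for Il1b, the smallest that 4 pairs allow.

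**Figure D3:**
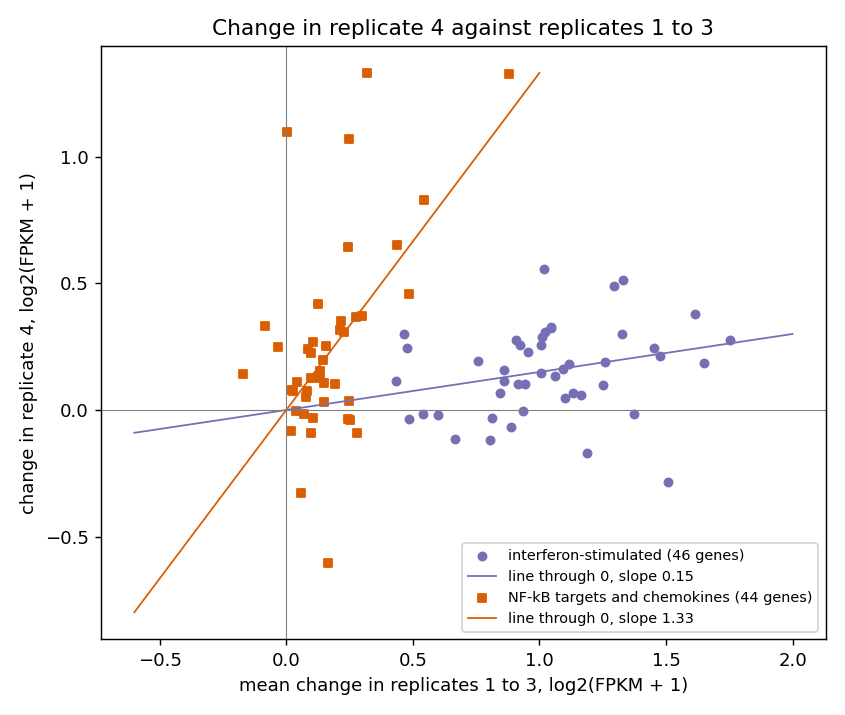
Difference in log2(FPKM + 1) between S100A8/A9 and vehicle in replicate 4 against the mean difference in replicates 1 to 3, with 1 point per gene and lines through 0 fitted by least squares. The 46 interferon-stimulated genes follow a slope of 0.15, and the 44 NF-kB targets and chemokines a slope of 1.33.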

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

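Of the tests in this part, those of scaling, cell type, endotoxin, table processing, the vehicle level and variation between pairs were chosen only after the results they bear on were seen. The comparisons with other splits of the libraries were chosen before those splits were run.

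The interferon-stimulated genes had a smaller difference in replicate 4 than in replicates 1 to 3. The median was -0.83 in a blocked limma model of all 4 pairs with a term for the difference between the tables. Replicate 4 is 1 pair, so the spread in this model comes from replicates 1 to 3 only, and the size of the difference is given without a test. A general shrinking of differences in the replicate 4 table is argued against, because NF-kB targets and chemokines had a slope of 1.33 (95% bootstrap interval 0.87 to 1.71, 44 genes) between replicate 4 and the mean of replicates 1 to 3, while interferon-stimulated genes had 0.15 (0.09 to 0.19, 46 genes). Genes of a list are not independent, so these intervals are too narrow, and Ifit1 had a lower ratio in replicate 4 without any pseudocount as well (1.56 against 3.35). A high interferon program already present in the replicate 4 vehicle culture is argued against as well, because the list's median percentile rank there was 49, against 67.2, 67.2 and 53.7 in the other vehicle libraries and 70.9 to 89.9 in treated replicates 1 to 3, a comparison across separately normalized tables. What stays open is ordinary variation between pairs, since the pair medians were 1.41, 0.92, 0.72 and 0.16 and the gap of replicate 4 was 0.446 of their range, short of an outlier with 4 pairs too few to decide, and that replicate 4 may differ in the cultures, the dose, the harvest time or the protein lot, none of which the labels give and none of which was tested.

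The higher interferon-stimulated genes of replicates 1 to 3 were weighed against 4 explanations. The authors' scaling of the libraries is argued against, since the lowest median over 4 other scalings was 0.958 against 1.02. For the 10 cell types with at least 5 tested markers, a larger share of a type that itself supplied the extra transcripts is argued against. The highest median among their marker lists was 0.071, for macrophages, far below the lower quartile of 0.86 of the interferon list. This comparison cannot tell whether a smaller gain of a type that acts on other cells raised these genes there. Whether plasmacytoid dendritic cells, mast cells and basophils, eosinophils, B and plasma cells, stromal cells and fibroblasts, or stem and progenitor cells had a larger share cannot be told from their 1 to 4 tested markers, whose highest median was 0.119 (stromal and fibroblast). Endotoxin carried by the recombinant protein could also raise interferon-stimulated genes through TLR4, and the NF-kB median of 0.148 cannot separate it from an action of S100A8/A9 at the same receptor, since the labels name no endotoxin control. An interferon response to S100A8/A9 itself therefore stays a hypothesis.

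Within-pair differences of 6 of 87 results had 1 of 4 pairs far from the others, where chance gives about 1 in 20. Acod1 stood at 1.085 in replicate 1, against 0.64 to 0.71 in the others, and Ly6a at 0.51 in replicate 1. Usp18 stood at -0.17 in replicate 4. Il1b stood at 0.83 in replicate 4 on the log2(FPKM + 1) scale, which understates changes of low genes. Its vehicle values were 1.85, 3.61, 6.75 and 29.1 FPKM in replicates 1 to 4. Its FPKM ratios were 1.69, 1.61, 1.52 and 1.80, so its fold in replicate 4 was close to the others. S100a8 stood at -0.15 in replicate 3, and the lysosome and phagocytosis list at 0.098 in replicate 3. The term for the difference between replicate 4 and replicates 1 to 3 rests on 1 pair in replicate 4, so its calls of single genes are not given.

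Other splits of the 6 libraries of replicates 1 to 3 number 10 with the real one, and 4 of these part all 3 pairs, so neither set can give a share under 0.05. The group-only fit called 0 genes, and the highest other split called 1. It called 6 lists, while the highest other split called 14. Of the 10 splits, 7 called at least 6 lists, the real one among them. This points to a structure of the samples, since the splits with 9 or more lists keep pairs together. The other splits that part all 3 pairs called 1, 1 and 0 lists. The size of the difference in the interferon list mean was 1.03, and 0.875 in the highest other split, which parts only 1 pair. In the other splits that part all 3 pairs, as the real one does, it was 0.538, 0.384 and 0.107. In the blocked fit the real split gave 59 genes and 11 lists, and the highest other split of the 4 gave 3 genes and 2 lists.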

How the results depend on the processing

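Quantile normalization, the pseudocounts, the 8-library group-only fit and the alternatives inside the blocked fit were chosen after the data were seen. The planned count fits (quasi-likelihood, Wald and voom) and TMM were not run because the values are not counts, and the planned RLE, upper-quartile and library-total settings were computed on FPKM. The planned use of the series table gave the same values. The interferon list stayed higher in each setting tried, with a median of 0.744 to 1.347, and its call was lost with an estimated correlation (median 1.015, adjusted p = 0.37, and 0.40 with the block) and with fry (median 1.015, adjusted p = 0.21, and 0.075 with the block). With all 8 libraries its median was 0.83. Without single libraries it lay between 0.744 and 1.347, and without single pairs between 0.817 and 1.195.

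The count of 0 genes without the block became 59 with the replicate block, and lay between 0 and 1 without single libraries, where Gm10260 was called without vehicle replicate 2. The blocked count of 59 became 3 with median-of-ratios factors, 0 with upper-quartile factors (996 at an unadjusted p under 0.05), 39 with a common sum, 3 with quantile normalization, 0 without a filter (1371 at an unadjusted p under 0.05, with 32091 genes tested), 90 with genes in both tables, 0 with all 8 libraries (931 at an unadjusted p under 0.05), 23 with a log2 change of at least 1 and 3 at an adjusted p under 0.01. The 1371 genes without a filter are fewer than the share of 0.05 that no change at all would give on average. The 3 genes with median-of-ratios factors and with quantile normalization were Ifit1, Rtp4 and Usp18. All 59 genes kept their sign in each of these fits that tested them, 57 of them in the fits limited to genes in both tables. Because the genes had been called in mostly the same libraries, a kept sign was largely fixed in advance and is no check of the calls. The count was 7 without replicate 3, 40 without replicate 1 and 98 without replicate 2. Acod1 had adjusted p-values between 0.0136 and 0.839 over these settings. The cause was not tested beyond the larger or smaller number of genes and libraries.

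The 6 lists without the block became 11 with the replicate block, 10 without a filter, 10 with all 8 libraries and the block, 0 with an estimated correlation and 0 with fry, and lay between 4 and 17 without single libraries. Of these, 12 were higher and 5 lower without vehicle replicate 3, 5 higher and 3 lower without S100A8/A9 replicate 1, 3 higher and 1 lower without vehicle replicate 2, and 6 higher and 1 lower without S100A8/A9 replicate 3. Without vehicle replicate 1 or S100A8/A9 replicate 2 none was lower. The 11 lists with the block became 0 with an estimated correlation and 0 with fry, and lay between 6 and 9 without single pairs (6 higher and 0 lower without replicate 2, 8 higher and 1 lower without replicate 1). The block changed no call beyond those given. The NF-kB list had medians between -0.001 and 0.243 without single libraries, the lowest without S100A8/A9 replicate 3. The inflammasome call was also lost with pseudocount 0.1 (adjusted p = 0.052), with a table term over all 8 libraries (0.064) and, with the block, without replicate 1 (0.12), and the call of the receptor and TLR4 list, with the block, without replicate 2 (0.076).

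None of the genes that changed direction was called. The change of Kit was -0.017 with median-of-ratios factors, -0.036 with upper-quartile factors, -0.006 with a common sum, -0.003 with quantile normalization and -0.001 with pseudocount 0.1. Stat3 was at -0.027 with upper-quartile factors and -0.018 with quantile normalization. Without single libraries, log2 changes ranged from -0.839 to 0.985 for S100a8, -0.794 to 0.837 for S100a9, -0.039 to 0.098 for Stat3, -0.135 to 0.056 for Tgfb1, -0.118 to 0.34 for Cd80, -0.014 to 0.177 for Cd86, -0.358 to 0.243 for H2-Ab1, -0.024 to 0.18 for Tlr4 and -0.56 to 0.108 for H2-DMb1. They ranged from -0.408 to 0.628 for Abca1, -0.031 to 0.643 for Tk1, -0.005 to 0.493 for Manf, -0.445 to 0.332 for Cd24a, -0.281 to 0.049 for Clec10a, -0.353 to 0.028 for Ccr2, -0.067 to 0.098 for Kit and -0.55 to 0.202 for Ear1. They ranged from -1.145 to 0.303 for Hba-a2, -0.105 to 0.691 for Pf4, -0.003 to 0.26 for Kdr, -0.221 to 0.452 for Acp5 and -0.003 to 0.367 for Ly6a. Leaving 1 library out of the unblocked fit unbalances the pairs, so genes that differ between pairs move. S100a8, for example, was at 9.72, 44.1 and 125 FPKM in vehicle replicates 1 to 3. The SE of its log2 change was 1.029 without the block and 0.09 with it. The cause of the other changes of direction was not tested.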

Other observations

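Replicate pairs differed from one another in myeloid marker levels by more than S100A8/A9 and vehicle did. Mean log2(FPKM + 1) of the neutrophil list was 2.68, 3.72 and 4.45 in the vehicle libraries of replicates 1, 2 and 3, and 2.80, 3.73 and 4.45 in the S100A8/A9 libraries. S100a8 itself was at 9.72, 44.1 and 125 FPKM in the vehicle libraries and 11.4, 52.5 and 113 FPKM in the treated ones. Macrophage markers were at 6.63, 5.76 and 5.08 with vehicle and 6.70, 5.82 and 5.18 with S100A8/A9. The mannose receptor gene Mrc1 was at 74.97, 33.1 and 12.1 FPKM with vehicle and 74.4, 31.3 and 12.3 FPKM with S100A8/A9, and Apoe at 263, 106 and 27.8 FPKM with vehicle and 238, 103 and 31.9 FPKM with S100A8/A9. Mrc1, Apoe and Hbb-bs were named after their values were seen. H2-Ab1 was at 670, 402 and 336 FPKM with vehicle. Erythroid genes were at 1.27, 1.81 and 4.52 with vehicle, and the replicate 3 libraries held Hbb-bs at 41.5 and 34.8 FPKM.

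The first principal component of the 6 libraries carried 46.6% of the variance and placed the libraries of a replicate number beside each other, at -19.2 and -23 for replicate 1, 1.7 and -0.6 for replicate 2, and 19.4 and 21.7 for replicate 3 (vehicle and S100A8/A9).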
